A study of Mus musculus with 2 samples.

How the data were processed

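Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse T helper 17 (Th17) cells, the interleukin-17-producing class of CD4 T cells, wild-type and grown in primary culture. The antibody was directed at REV-ERBα, a nuclear receptor of the circadian clock that represses transcription, and input DNA from the same kind of cells was sequenced as the control. The labels give 1 ChIP sample and 1 input sample, so no comparison below has a replicate behind it. The only processed file used was the peak list of the ChIP sample. Input entered only through the values that this list gives for each peak.

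The tools CASAVA 1.8.2, Bowtie (an aligner) and HOMER and the genome build mm9 are named per the submitters' processing notes. The versions of Bowtie and HOMER, and the treatment of repeated reads before alignment, are not given in the sources used here. Peaks were called by the authors with HOMER findPeaks on the ChIP library against the input library, per the file headers. The fragment length was 306 bp, and every listed peak has an end minus start of 306 bp. Peaks could not lie closer than 612 bp. The caller's false discovery rate was 0.001, which set a threshold of 9 tags; all scores were at least 9, while the total tags of 55 peaks were 7 or 8. A peak then had to reach 4-fold and a Poisson p of 1e-04 over input, and the same over the surrounding 10000 bp. At most 1 tag per bp was considered in the search.

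The list holds several units. Total tags are counts of ChIP tags, deposited without normalization. The normalized tag count is a signal that the authors scaled to 10000000 tags; for all 8884 peaks it equalled the tag count times this number over the library total to within 0.06. Input tags are a signal scaled by the authors to the ChIP depth, per the file headers. The deposited fold values are linear ratios of ChIP to scaled input tags or to the local region. The p-values are the authors' Poisson values and were not tested again. The deposited score is the caller's own peak height. The total of the input library and the width over which its tags were counted are not given in the sources used here. Dividing tags by the listed fold gave input values in steps of 0.945 scaled tags. All 7392 peaks above the lowest input value lay on whole steps to within a relative 0.02, and the other 1492 peaks were listed at 0.5 (0.473 before rounding, or 0.5 of a step), which was read as no input tag. The fold of those peaks depends on this lowest value and is not a measured ratio.

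Numbers of peaks, tags and folds were tabulated with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Counts carry exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals; both cover counting error only, and treat peaks as independent. A fold interval for a named peak was taken from the exact binomial interval of its ChIP and input tags. Peak density on a chromosome is the number of peaks over the distance from its first to its last listed peak, because no table of mm9 chromosome lengths was used. Gene density is the number of genes over the same distance. Gene numbers per chromosome came from a RefSeq table of the GRCm38.p6 assembly, from which only the symbol, class and chromosome of each gene were used; it holds 21631 protein-coding genes on chromosomes 1 to 19 and X, of which 1482 have symbols of odorant, vomeronasal or trace amine receptors. Correlations over the 19 autosomes have permutation p-values from 100000 resamples, two-sided, as have comparisons of mean tag ranks.

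For spacing, the share of peaks whose midpoint lay within 10 kb of another was set against 100 random placements of the peaks between the first and last peak of their chromosome. It was also set against 100 placements in which each peak was moved at random by up to 500 kb. This keeps regional density on longer scales and smooths it on shorter ones. Both kept the caller's minimum distance. The procedure was tested on simulated peaks, 8884 in each set. For sets with regional density alone, the listed peaks were moved once by up to 500 kb and then compared with peaks moved again. The 20 sets used to fix a limit gave an excess of up to 2.17 percentage points, because moving also smooths the density. Only an excess above 1.5 times that value, 3.26, was counted. The first move had already smoothed these sets, so the limit can be too low for density that varies over less than 500 kb. With this limit an excess was found in 20 of 20 sets with planted pairs. Those pairs were planted on peaks placed uniformly along their chromosomes, so the result does not show that pairs can be told from uneven density. In 20 of 20 further sets with regional density alone, the excess lay within the limit. These came from the same listed peaks by the same steps as the sets that fixed it. They are therefore no independent check of it. Chains of peaks with at most 10 kb from each midpoint to the next are called clusters.

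The design written before the data were examined also held the distance of peaks to transcription starts, binding motifs in the peaks and 14 lists of clock, helper T cell, metabolic and other genes. These were not analysed here. They need mm9 sequence and gene positions, and coordinates were not carried between builds. As a check on the builds, 5.30% of peak midpoints lay within 1 kb of an end of a protein-coding gene of GRCm38.p6 when the coordinates were taken as they stand, against 4.03% to 4.37% after shifts of 500 or 1000 kb either way. No gene names are therefore given to peaks. The planned rule for named genes could not be applied, and the regions named are the first by rank on tags, cluster size, window density or gap length. All analyses of chromosomes and spacing, with their alternatives, were chosen after the peak list was seen; the peak filters were planned. The peak list is given in mm9 coordinates, as deposited.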

Results

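Binding of REV-ERBα in mouse Th17 cells was profiled by ChIP-seq. REV-ERBα is a nuclear receptor of the circadian clock that acts as a repressor, and it shares its DNA element with the receptor RORγt, the transcription factor that defines Th17 cells. The series asks where REV-ERBα is bound in these cells. It holds 1 ChIP sample and 1 input sample. The ChIP library had 6390234 tags, and the authors' peak list holds 8884 peaks in mm9 coordinates. With no second ChIP sample, none of the values below has a replicate check, and all intervals cover counting error only. The peaks could not be assigned to genes here, so they are described by position. The only control was input DNA and motifs were not examined, so whether each peak reflects REV-ERBα itself was not tested.

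REV-ERBα peaks were numerous but held few tags. Together they held 161147 tags, 2.52% of the library. The median peak had 15 ChIP tags, with quartiles of 12 and 20, and the 95% Poisson interval of a count of 15 runs from 8.40 to 24.7. In the authors' normalization to 10000000 tags the median was 23.5. The caller's score was 9 at least, and 2307 of the 8884 peaks had a score of 9 or 10. The caller had started from 14274 putative peaks. Of these, 3533 (24.8%) failed the comparison with input and 1857 (13.0%) failed the comparison with the local region. The remaining 62.2% make up the list.

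Every listed peak exceeded input by at least 4-fold, which is the authors' filter. The median fold over scaled input was 10.6, with quartiles of 6.35 and 18.0. At least 8-fold enrichment was listed for 5468 peaks (61.5%), at least 16-fold for 2499 (28.1%) and at least 32-fold for 536 (6.03%). Enrichment over the local region was lower, with a median of 7.78. In 1492 peaks (16.8%) the input was listed at the lowest value, 0.5 scaled tags, so that the fold of these peaks is set by that value. They made up 25% of the 2708 peaks of at most 12 tags and 8.54% of the 1791 peaks of at least 22 tags. The 4-fold filter keeps a weak peak only where its input is low.

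**Figure D1:**
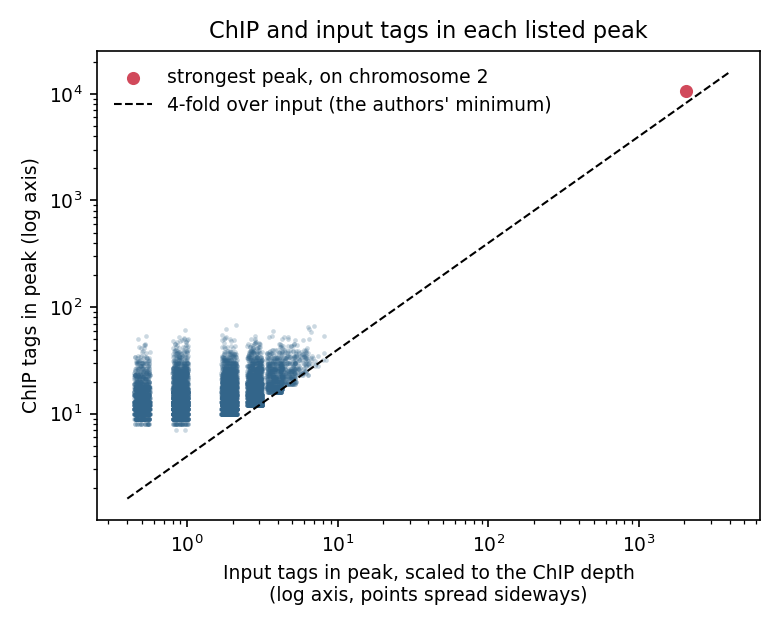
ChIP tags against scaled input tags in each of the 8884 peaks, both on log axes; points are spread sideways because input takes few values, and the dashed line marks 4-fold. The strongest peak, on chromosome 2, lies apart from the others with 10556 ChIP tags and 2064.5 scaled input tags.

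The peak with the most tags lay on chromosome 2 at 98506881 to 98507187. It held 10556 ChIP tags, 155 times the next peak, and 6.55% of all tags in peaks. Its input was also high, at 2064.5 scaled tags, where no other listed peak exceeded 7.6. Its fold over input was 5.11 (95% interval 4.88 to 5.35), and 10.3% of the other peaks had a lower fold. That interval takes tags as independent draws, which may not hold in a region with 34.5 tags per bp, so it can be too narrow. Without this region the peaks held 2.36% of the library.

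The next strongest peak lay on chromosome 1 at 146086208 to 146086514. It had 68 tags (95% interval 52.8 to 86.2) and was 36.0-fold over input, with an interval of 9.58 to 303 because it rests on 2 input tags. A pair of strong peaks lay 11.7 kb apart on chromosome 3. The peak at 88313991 to 88314297 had 67 tags and was 8.86-fold over input, and the peak at 88325739 to 88326045 had 65 tags and was 11.5-fold over input. On chromosome 18 the peaks at 65482121 to 65482427 and at 34918804 to 34919110 had 63 and 61 tags. The peak on chromosome 9 at 107471124 to 107471430, also with 63 tags, had the highest enrichment over its local region in the list, 43.4-fold. The other peaks of at least 54 tags lay on chromosome 7 at 106982309 (60 tags), chromosome 2 at 11538458 (59 tags) and chromosome 11 at 86437821 (55 tags), with 4 peaks of 54 tags on chromosome 11 at 4338247, chromosome 12 at 100748375, chromosome 15 at 81131622 and chromosome 6 at 47571097. The tag counts of these 13 peaks overlap within their intervals, so their order is not resolved. The highest listed fold over input, 114, belonged to the peak of 54 tags on chromosome 6, with input at the lowest value.

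Peaks were found on chromosomes 1 to 19 and X, and none on Y. Peak density differed between chromosomes. It averaged 3.71 ± 0.735 peaks per Mb over the autosomes (SD across 19 chromosomes). Chromosome 11 was the densest, with 697 peaks and 5.87 peaks per Mb (95% interval 5.44 to 6.32). Chromosome 9 followed with 4.48, then chromosome 19 with 4.21 and chromosome 2 with 4.13. Chromosomes 18 and 14 had the lowest autosomal densities, 2.68 and 2.69. The X chromosome had 112 peaks, 1.26% of the list, and 0.702 peaks per Mb (95% interval 0.578 to 0.845). This was 0.189 of the autosomal mean and below the lowest autosome. The ratio was 0.228 among peaks at least 8-fold over input and 0.0858 among the peaks at or above the median tag count. X peaks also had fewer tags than autosomal peaks, with medians of 13 and 15 (difference in mean rank tested by permutation, two-sided p = 1.0e-05, the smallest that 100000 resamples can give). That test treats peaks as independent and describes this library.

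**Figure D2:**
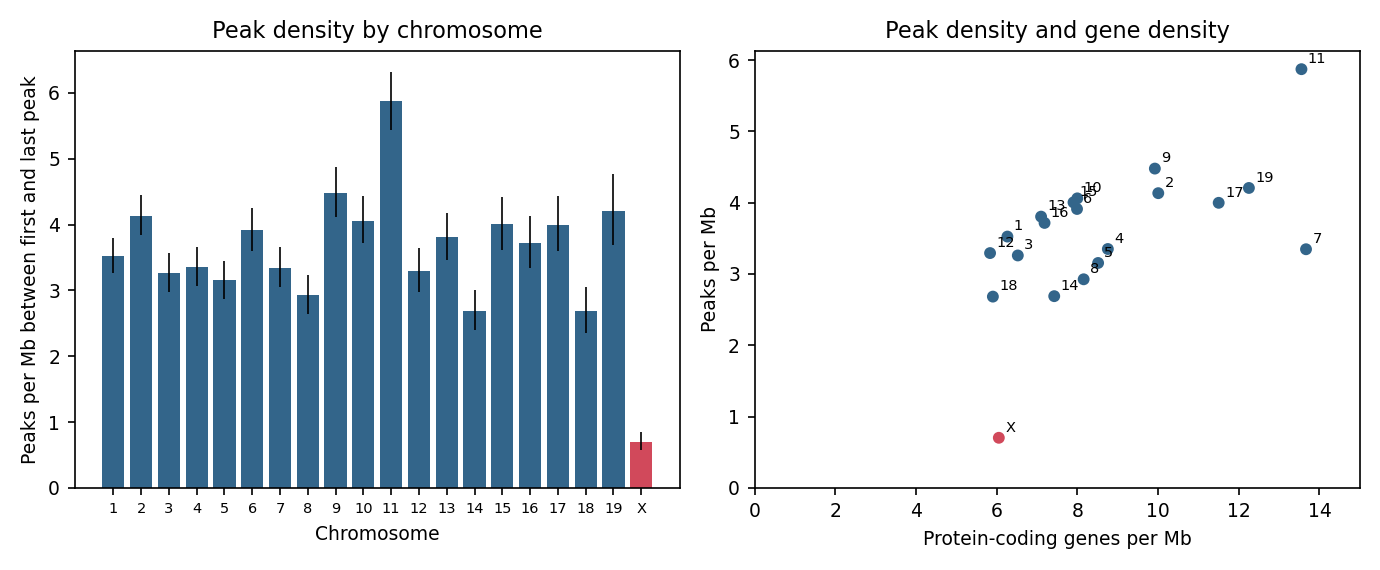
Left, peaks per Mb on each chromosome with 95% Poisson intervals; right, peaks per Mb against protein-coding genes per Mb, each point a chromosome. Chromosome 11 is highest on both panels' peak axis at 5.87, and the X (red) lies far below the autosomes at 0.702.

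Across the 19 autosomes, peak density rose with gene density. Both were divided by the distance from first to last peak, and the permutation p-values below do not account for this shared divisor. Pearson's r between peaks per Mb and protein-coding genes per Mb was 0.60 (permutation p = 0.0061, Benjamini-Hochberg adjusted 0.0092 over 3 gene definitions) and Spearman's rho was 0.53 (permutation p = 0.021, adjusted 0.031). Without chromosomes 7 and 11, the 2 farthest from the median gene density, r was 0.60. These 2 chromosomes moved r in opposite directions: without chromosome 7 alone r was 0.76 (permutation p = 0.00019) and rho 0.64 (p = 0.0048). Chromosome 11 alone carried part of the relation: without it r was 0.42 (permutation p = 0.085) and rho 0.47 (p = 0.049). Without chromosome 18, rho was 0.46 (permutation p = 0.057) and r 0.56 (p = 0.016). Chromosome 7 had the lowest autosomal number of peaks per protein-coding gene, 0.245, against a mean of 0.439 ± 0.0877 (SD, 19 autosomes). Chromosome 7 stayed the lowest autosome, at 0.308, when odorant, vomeronasal and trace amine receptor genes were left out. With these receptor genes left out, r was 0.64 (permutation p = 0.0034), but it fell to 0.30 without the 2 chromosomes then farthest from the median, 11 and 19. The X carried 0.116 peaks per protein-coding gene (95% interval 0.0955 to 0.140), below every autosome.

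Within chromosomes the peaks were concentrated in a minority of regions. In windows of 1 Mb over all chromosomes the mean was 3.47 peaks and the median 1. Within each autosome the variance between windows was 4.13 to 9.58 times that chromosome's mean. No peak lay in 931 of 2400 autosomal windows (38.8%), where Poisson distributions with each chromosome's own mean give 74.8 empty windows. On the X, 123 of 161 windows were empty, where 80.3 are expected in the same way. The 256 densest of all 2561 windows held 41.8% of the peaks. The highest number in a window, 30, was on chromosome 15 from 58000001 to 59000000, and the windows starting at 59000001 and 62000001 on the same chromosome had 25 and 27. The window on chromosome 11 from 86000001 to 87000000 had 28 and includes a peak of 55 tags. Windows with 25 to 27 peaks also lay on chromosome 3 at 95000001 and 52000001, chromosome 11 at 4000001, chromosome 17 at 84000001 and chromosome 8 at 35000001. The longest stretch between neighbouring peaks was 18.9 Mb, on chromosome 4 from 63596662 to 82494739. Of the 10 longest stretches, 4 were on the X, the longest of them 16.9 Mb from 54430783 to 71345334. Stretches that could not be mapped are not marked in the peak list.

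**Figure D3:**
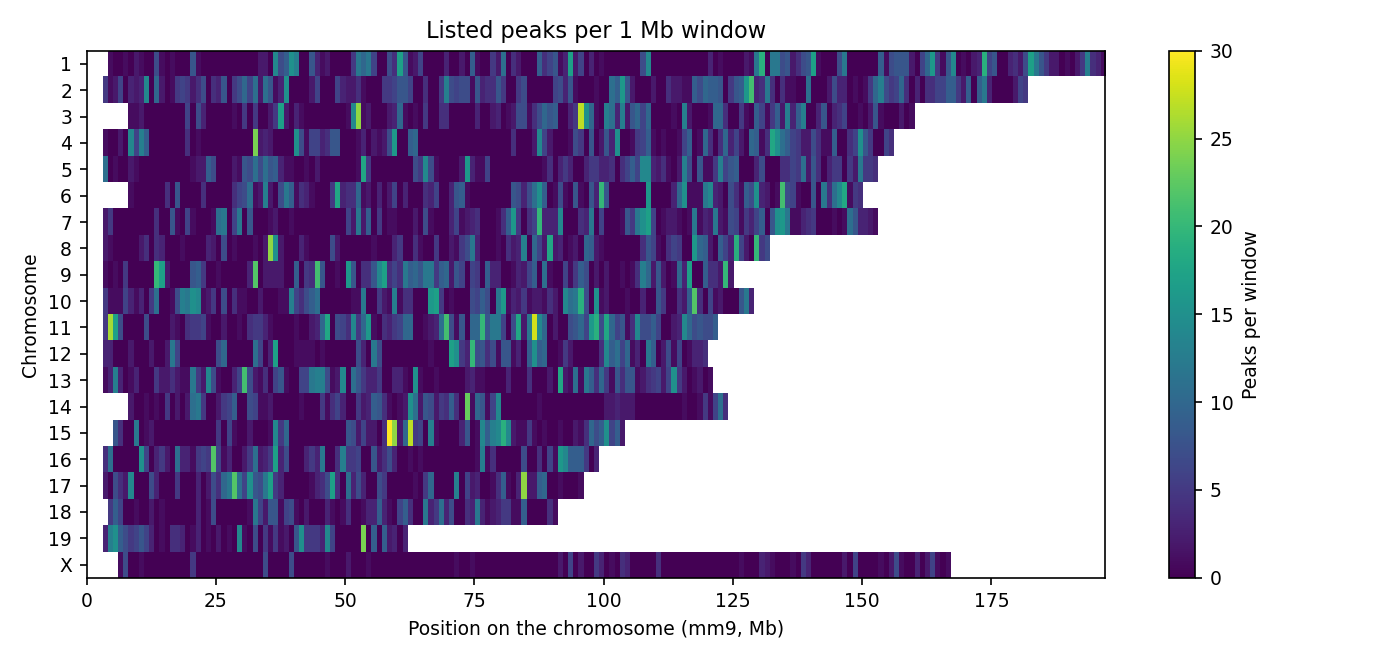
Listed peaks per 1 Mb window along each chromosome in mm9 coordinates; white lies outside the first and last peak. The brightest window, with 30 peaks, is on chromosome 15, and the X is dark over most of its length.

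Peaks also lay near each other at a finer scale. A neighbour within 10 kb was found for 2995 peaks, or 33.7% (95% interval 32.7 to 34.7). Random placement on the same chromosomes gave 6.79% ± 0.306 (SD, 100 placements), and moving each peak by up to 500 kb gave 15.2% ± 0.520 with a highest value of 16.6%. The observed share was 2.22 times the mean of the moved peaks. Gaps of 3000 to 10000 bp numbered 1067, against 529 in the moved peaks on average and 588 at most. Gaps of 1000 to 3000 bp numbered 476 against 157, and those under 1000 bp 123 against 30.4.

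**Figure D4:**
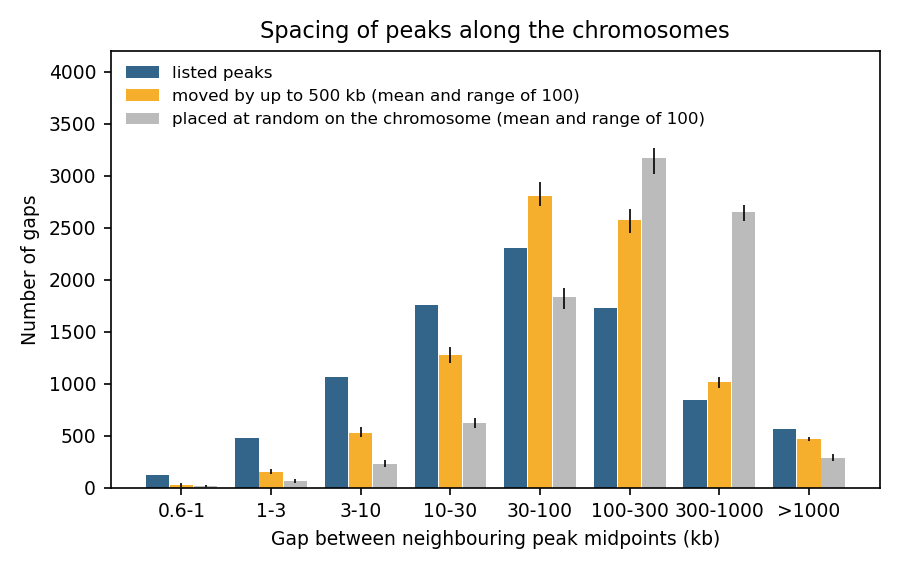
Number of gaps between neighbouring peak midpoints by length, for the listed peaks (blue), peaks moved by up to 500 kb (yellow) and peaks placed at random on their chromosome (grey); lines give the range of 100 placements. Listed peaks exceed both placements in every class up to 30 kb, with 1067 gaps of 3 to 10 kb against 529 in moved peaks.

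The peaks formed 1329 clusters of at least 2. Clusters of at least 3 peaks numbered 263 and held 9.71% of all peaks, where moved peaks gave 64.4 ± 7.83 such clusters and at most 86. Clusters of at least 5 numbered 11, against 1.02 ± 1.08 and at most 5. The cluster with the most peaks, 8, spanned 29.2 kb on chromosome 5 from 53792424 to 53821655; its peaks had 13 to 37 tags each and 220 in all. The moved placements also reached a cluster of 8, so the size of this cluster alone does not set it apart from regional density. Clusters of 5 peaks included chromosome 12 from 74977722 to 75002436 with 131 tags, chromosome 8 from 89376379 to 89395021 with 128, chromosome 1 from 93939012 to 93961086 with 126, and chromosome 15 from 9485664 to 9509737 with 119.

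Stronger peaks had close neighbours more often. The share with a neighbour within 10 kb was 21.6% (95% interval 19.7 to 23.5) in the weakest 20% of peaks by tags, with ties split by their order in the list. With ties kept together, it was 24.0% (22.4 to 25.7) among the 2708 peaks of at most 12 tags. It was 39.1% (36.8 to 41.4) in the 20% next to the strongest and 45.2% (42.9 to 47.6) in the strongest 20%. Peaks with a neighbour had a median of 16 tags and the others 14 (difference in mean rank by permutation, two-sided p = 1.0e-05, the smallest possible here). Neighbouring peaks are not independent, so this p describes the list rather than repeated experiments. The local filter, which removed 1857 putative peaks, compares each peak with the 10000 bp around it, so that neighbouring peaks enter each other's background. A weak peak beside another can fail it for that reason, which would leave the stronger ones among peaks with a neighbour. The trend with strength was not separated from this filter.

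**Figure D5:**
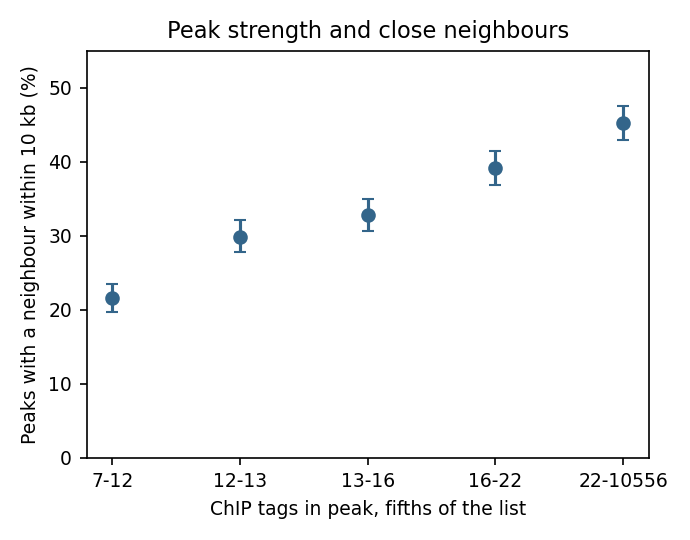
Share of peaks with another peak within 10 kb, for 5 equal parts of the list by ChIP tags in the peak (range of tags on the axis, ties split by their order in the list); lines are Clopper-Pearson 95% intervals. The share rises from 21.6% to 45.2%.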

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

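The peak filters were planned before the data were examined for the number of peaks; all other alternatives were chosen after seeing the data. Requiring at least 8-fold over input left 5468 of 8884 peaks, and keeping the stronger peaks, at or above the median count, left 4554. The X density relative to the autosomal mean, 0.189 over all peaks, was 0.228 among the peaks with at least 8-fold enrichment and 0.0858 among the stronger peaks; the cause was not tested. Leaving out peaks off the assembled chromosomes removed none, so it tests nothing. Removing only the strongest peak is counted among the alternatives below, though it could change little. Leaving out the peaks with the most input left 8557 peaks and an X ratio of 0.195. The correlation of peak density with gene density stayed positive with a permutation p under 0.05 in the 6 alternatives that changed peaks or genes (r from 0.48 to 0.64). Its p did not stay under 0.05 without chromosome 11 (r = 0.42). The r of 0.64, with receptor genes left out, fell to 0.30 without chromosomes 11 and 19. The excess of close neighbours over moved peaks, 2.22-fold, ran from 1.53-fold, with peaks moved by up to 100 kb, to 3.23-fold, with peaks moved by up to 2 Mb, and stayed above the highest placement in the 8 alternatives that changed peaks or distances. Peaks with a neighbour ranked higher by tags in 6 such alternatives. All 6 used peaks that had passed the local filter, so they cannot test whether that filter gave the difference. With ties in tags kept together, the share with a neighbour was 24.0% at the weak end, against 21.6%, and 45.2% at the strong end, as before. The settings listed beforehand for transcription starts, motifs and gene lists were not run, since mm9 sequence and annotation were not used here. Leaving out replicates was not possible with 1 ChIP sample. At 6390234 tags, a site with a few tags stays under the threshold of 9, so regions without a peak are not shown to be unbound.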

Other observations

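The tests of gene density and dosage of the X and those of spacing were written down before their results were seen; the test on the strongest region, and the ratios over all 112 X peaks with those expected at 0.5 of the tags, were chosen after.

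The X chromosome held 0.702 peaks per Mb against 3.71 on the autosomes. Lower gene density does not account for all of it, since the X had 0.116 peaks per protein-coding gene with a 95% upper bound of 0.140, and the lowest autosome had 0.245. Lower dosage, as with 1 X copy per cell, stays open. Over all 112 X peaks the local ChIP background was 0.815 of that at autosomal peaks of equal tag count (bootstrap 95% interval 0.753 to 0.880). The input ratio was 0.868 (0.757 to 0.983). Both were below the lowest autosome, which had 0.926 for the local background and 0.905 for input. The interval of the X input ratio includes 0.905, so only the local ratio was clear of the lowest autosome. Autosomal peaks with 0.5 of their tags and background would give 0.774 and 0.809, inside these intervals. Neighbouring peaks enter each other's local background and the X had fewer peaks per Mb. The local ratio therefore cannot separate dosage from sparser peaks. Among the 9 X peaks of at least 20 tags the ratios were 0.873 (0.608 to 1.19) and 0.995 (0.501 to 1.58). The first lay inside the range of single autosomes against the others, 0.846 to 1.16. It met the bound of 0.8 set beforehand against dosage, and its lower end met the bound set for the interval. These bounds took no account of background rising with tag count. The lowest ratio on leaving out 1 X peak was 0.718, without the peak at 166433327 to 166433633. Autosomal scores thinned to 0.5 left 29.6% of peaks at the threshold, against the 18.9% of autosomal density on the X, but the filters over input and over the local region were not part of that simulation, so it excludes nothing. Fewer bound sites and poorer mapping on the X were not tested, and the labels do not give the animals' sex.

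The region on chromosome 2 from 98506881 to 98507187 held 155 times the tags of the next strongest peak. A candidate explanation is DNA over-represented in the mapping, such as copies of a repeat collapsed in the assembly. The input also reached 2064.5 scaled tags there, 272 times the highest other listed peak. The other listed peaks had at most 68 tags and passed the 4-fold filter, which bounds their input. Putative peaks that failed this filter are not listed, so other regions of high input cannot be seen. The score, for which at most 1 tag per bp is considered, was 0.0352 of the tag count, against a median of 0.88 for the other peaks. With 34.5 tags per bp in the region, this low ratio follows from the cap and is no separate evidence. The remaining 5.11-fold enrichment over input has no explanation tested here, and no biological explanation was tested.

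Close spacing of peaks exceeded what regional density gave when peaks were moved by up to 500 kb. The share with a neighbour within 10 kb was 33.7% against at most 16.6% in moved peaks, an excess of 18.5 percentage points over their mean. The simulated sets with regional density alone that fixed the limit gave at most 2.17. However, those sets were listed peaks already moved once, with their finer density smoothed. The 2.17 therefore does not bound what density varying over less than 500 kb can give. Sites listed as several peaks less than 3 kb apart do not account for all of it either, because gaps of 3 to 10 kb numbered 1067 against at most 588. Broader sites would themselves give such gaps, so this count cannot decide on them. As a hypothesis, REV-ERBα may bind groups of nearby elements in the same regulatory regions. Density that varies over less than 500 kb, such as clusters of open chromatin, would give the same spacing. Moving peaks by only up to 100 kb lowered the excess to 1.53-fold. A shorter move keeps more peaks near their neighbours whatever the cause of the clustering, so this drop favours neither. Open chromatin was not measured here.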
